A study of Mus musculus with 76 samples.

How the data were processed

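RNA was sequenced from the dorsal forebrain of C57BL/6J mouse embryos at embryonic day 16. Per the labels, parents were treated with α-cypermethrin or vehicle for 28 days, a first run of 7 days and then 3 cycles of 2 days without and 5 days with treatment, and were then mated. The 76 libraries form 7 groups by exposed parent and dose, as labelled, in batch 1 (18 female and 16 male embryos) and batch 2 (18 and 24). The labels give neither litter nor date nor the unit of the dose.

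The deposited table holds expected counts (expected_counts), estimated reads per gene that the authors obtained with Trim Galore 0.5.0 and Salmon 1.10.1 on mm10. Its values are whole numbers. How estimates were summed to genes and made whole, the annotation release and the filter are not stated. Each of the 14823 genes has at least 10 counts in 3 libraries. Symbols and positions came from GENCODE M21 (GRCm38) by gene ID, with a symbol for 14810 genes and none for 13. Library totals ran from 17.7 to 41.4 M counts, with 17 libraries above 19.9 M. At this depth a gene of 1 CPM has about 19 counts in a library of median size. No pair of libraries was identical (smallest scaled chi-square per gene 4.24), and the first principal component held 16.6 percent of the variance. The labelled sex was checked on Ddx3y, Eif2s3y, Kdm5d and Uty, since Xist is not in the table. Replicate numbers were checked as pairs and do not pair libraries across groups, so that no paired test was used.

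Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on group (14339 genes kept, 484 removed), TMM factors, and a robust quasi-likelihood fit on all 76 libraries with group, batch and sex as terms. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, over the genes of a comparison. The comparisons were each exposed group against Ctrl, a joint test of the 6, dose 10 against 0.3 per parent, mother against father per dose, non-additivity (both minus mother minus father plus Ctrl), sex by exposure, batch by exposure and male against female. Values within a batch come from a fit with a separate mean for each group and batch, while the settings of batch 1 or batch 2 alone are new fits of those libraries. Normalised CPM are on TMM-scaled totals. Comparisons of exposed groups with each other use no Ctrl library, while the 6 comparisons with Ctrl share its 12 libraries. Similarity due to the shared Ctrl libraries was taken from 20 simulations without group differences, in which each gene was drawn independently.

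The 41 gene lists (905 genes) were written, like the groups, the comparisons, the first set of other settings and the rule for named genes, before the data were examined. Those for cell types cover radial glia, intermediate progenitors, upper-layer neurons, deep-layer neurons, interneurons and ventral forebrain, striatal neurons, diencephalon and Cajal-Retzius cells. They also cover cortical hem and hippocampus, oligodendrocyte precursors, early astrocytes, microglia and macrophages, endothelial cells, pericytes and smooth muscle, meninges and fibroblasts, choroid plexus and erythroid cells. The others cover the pathways named with their results. Each list was tested with camera (limma 3.58.1, 2-sided, preset correlation 0.01), with an estimated correlation and fry beside it, and with GC and length offsets on ranked edgeR statistics. P-values were adjusted over the 41 lists of a comparison, and those of members also over the list alone, with counts given where they differ. Shares of counts were compared by an exact permutation test within batches, 2-sided. It enumerates all rearrangements, and p was adjusted over all measures and groups. The rule named, per exposed group, the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 1 and the same sign in both batches. It named for other comparisons the 5 genes of lowest p, and per list up to 4 members of lowest p in Maternal_10Cyp, the group with the most calls, and for erythroid and diencephalon markers also in Paternal_0.3Cyp; predicted and clone-named genes were counted but not named.

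Other settings fixed then were DESeq2 size factors, no filter, DESeq2 1.42.0, limma voom with quality weights, only the groups compared, no batch term and the replicate number as a block. Further ones were 2 surrogate variables (sva 3.50.0), each batch alone, and leaving out each library in turn. Added after seeing the data were the log2 ratio of embryonic (Hbb-y, Hba-x) to adult globin counts as a covariate (pseudocount 0.5) and counts thinned to 17.7 M. Also added were offsets for GC content and transcript length (14327 genes), and leaving out libraries more than 3 MAD above the median in embryonic globins (3) or diencephalon markers (5). The methods were tested on simulated data. With the spread and group sizes of Both_10Cyp and Ctrl, 46 of 50 genes changed 1.5-fold were called and 6 of 14139 unchanged ones. Camera ranked a raised list first and called 0 other lists. No library was left out.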

Results

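RNA was measured by sequencing in 76 libraries of dorsal forebrain, the part of the embryonic brain that holds the developing cortex, from C57BL/6J mouse embryos at embryonic day 16. Before mating, the fathers, the mothers, both or neither had been exposed to α-cypermethrin, a pyrethroid insecticide, at a dose labelled 0.3 or 10, for which the labels give no unit. The groups were Ctrl (n = 12, pairs given vehicle), Paternal_0.3Cyp (n = 12), Maternal_0.3Cyp (n = 12), Both_0.3Cyp (n = 12), Paternal_10Cyp (n = 10), Maternal_10Cyp (n = 8) and Both_10Cyp (n = 10). Totals ran from 17.7 to 41.4 M counts per library, with a median of 19.2 M. They were not even across groups: 17 libraries held more than 19.9 M, among them all 10 of Both_10Cyp, 4 of Paternal_10Cyp, 2 of Maternal_0.3Cyp and 1 of Maternal_10Cyp, and no Ctrl library. Positions are on mm10, and every value after ± in the comparisons is a standard error of a log2 fold change unless SD is written. The title of the series names autism and stress vulnerability, and the comparisons with Ctrl ask which genes of the embryo's brain differed after the exposure of a parent. No litter is labelled, so that littermates are counted as separate replicates and the p-values would be too small if littermates resemble each other.

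In embryos of fathers exposed at dose 0.3, the embryonic globin gene Hbb-y and the progenitor genes Hmga2 and Neurog1 rose. Hbb-y (ENSMUSG00000052187; chromosome 7, 103851749 to 103853216), an embryonic beta-like globin, rose by a log2 fold change of 4.53 ± 0.88 (SE, n = 12 against 12), from 0.224 ± 0.309 in Ctrl to 7.79 ± 20.2 in Paternal_0.3Cyp (normalised CPM, SD, n = 12 and 12). The rise of Hbb-y was led by 2 libraries, replicate 4 with 69.7 CPM and replicate 3 with 18.8, and without the libraries high in embryonic globin it was 1.06 (edgeR quasi-likelihood adjusted p = 0.256). Hmga2, a chromatin protein abundant in young progenitor cells, rose by 1.33 ± 0.30 and Neurog1, a proneural transcription factor, by 1.69 ± 0.39, and each lay above the Ctrl mean in 10 of 12 exposed libraries. Replicates 4 and 3 led here too, with 14.4 and 9.12 CPM of Hmga2 and 13.4 and 8.22 of Neurog1, and without the libraries high in embryonic globin the values were 0.70 and 1.02. Transcription factors that pattern the embryo also rose: Tfap2b (2.86 ± 0.73), Irx1 (1.49 ± 0.45), Irx3 (1.22 ± 0.34) and Mab21l2 (1.33 ± 0.49). For these 4 genes 1 library led, replicate 9, whose Tfap2b level was 86.2 CPM where the next library of the group had 9.09; by limma Mab21l2 had -0.017. The other rising genes of the rule were Prph (1.09 ± 0.22), a neuronal intermediate filament, Robo3 (0.96 ± 0.33), an axon guidance receptor, and Hist1h2ag (1.004 ± 0.26), a histone gene.

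The astrocyte genes Gfap and Aqp4 and the activity-dependent gene Egr4 fell in the same embryos. Gfap, a filament protein, and Aqp4, a water channel, had log2 fold changes of -0.87 ± 0.30 and -0.79 ± 0.26. Egr4, an immediate early gene, fell (-1.07 ± 0.28) and was below the Ctrl mean in 12 of 12 libraries. Ptk2b, a calcium-responsive tyrosine kinase, fell (-0.81 ± 0.21), from 20.3 ± 6.55 in Ctrl to 11.4 ± 5.41 in Paternal_0.3Cyp (normalised CPM, SD, n = 12 and 12). The rule also named Edn1 (-1.03 ± 0.26), the peptide endothelin 1, Pcdha8 (-1.04 ± 0.30), a clustered protocadherin, Slc22a3 (-0.73 ± 0.26), an organic cation transporter, and Myo3b (-0.81 ± 0.19), Atp13a5 (-0.76 ± 0.23) and Mlip (-0.75 ± 0.20). In all, 3961 genes differed from Ctrl, 2206 higher and 1755 lower, out of 14339 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The named genes had adjusted p from 0.00178 to 0.0347 by edgeR quasi-likelihood; the median absolute log2 fold change of all genes that differed was 0.24, and 307 reached 0.5. The count was 1 within batch 1 (edgeR, 2822 at an unadjusted p under 0.05) and 2383 within batch 2, 44 with the ratio of embryonic to adult globin as a covariate, 0 when edgeR was given these groups alone (3928 at an unadjusted p under 0.05; DESeq2 on all groups 4130, limma 2841) and 0 with 2 surrogate variables (1592 at an unadjusted p under 0.05). It was 2592 without replicate 4, 2262 without replicate 8, 1788 without the 3 libraries high in embryonic globin and 2175 without the 5 high in diencephalon markers.

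In embryos of mothers exposed at dose 0.3, the proneural genes Neurod4 and Neurog1 rose, and Aqp4 and Nkx2-2, genes of glia, fell. Neurod4 (ENSMUSG00000048015; chromosome 10, 130268152 to 130280240), a proneural transcription factor of intermediate progenitors, rose by 0.69 ± 0.15 (SE, n = 12 against 12) and lay above the Ctrl mean in 12 of 12 libraries, from 2.94 ± 0.789 in Ctrl to 4.77 ± 0.803 in Maternal_0.3Cyp (normalised CPM, SD, n = 12 and 12). Neurog1 rose by 1.03 ± 0.40, and Dmrt3 and Wnt3a, a patterning transcription factor and a signal of the cortical hem, rose by 0.70 ± 0.22 and 0.91 ± 0.28. Dscc1 and Ska1, which act in sister chromatid cohesion and at the kinetochore, rose by 0.68 ± 0.16 and 0.67 ± 0.16. The remaining rising genes were Crabp2 (0.67 ± 0.25), a retinoic acid binding protein, Gcg (0.69 ± 0.14), the proglucagon gene, and Myzap (0.78 ± 0.23) and Kctd14 (0.75 ± 0.17). Among falling genes, Egr4 (-1.14 ± 0.28), Aqp4 (-1.001 ± 0.27) and Ptk2b (-0.89 ± 0.21) were named as in Paternal_0.3Cyp. Nkx2-2, a transcription factor of the oligodendrocyte lineage, fell (-1.07 ± 0.31), and Slc25a18, a mitochondrial glutamate carrier (-0.95 ± 0.28). Kctd16, an auxiliary subunit of the GABA-B receptor, fell (-1.01 ± 0.24), and Epha10, of the ephrin receptor family (-0.94 ± 0.28). Nwd2 fell (-1.01 ± 0.23), from 24.1 ± 8.80 in Ctrl to 12.1 ± 2.89 in Maternal_0.3Cyp (normalised CPM, SD, n = 12 and 12), beside Creg2 (-0.91 ± 0.27). With 2 surrogate variables Epha10 and Creg2 turned to 0.040 and 0.030. In all, 3404 genes differed from Ctrl, 1564 higher and 1840 lower, out of 14339 tested (edgeR quasi-likelihood). The named genes had adjusted p from 0.00317 to 0.0481 by edgeR quasi-likelihood; the median absolute log2 fold change of all genes that differed was 0.25, and 343 reached 0.5. The count was 0 within batch 1 (edgeR, 1207 at an unadjusted p under 0.05) and 3025 within batch 2, 170 with the globin ratio as a covariate, 0 by edgeR with 2 surrogate variables (1070 at an unadjusted p under 0.05; DESeq2 without them 3577, limma 4975) and 2166 without Ctrl replicate 7.

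Where both parents were exposed at dose 0.3, Dscc1, Tk1 and Gmnn, genes of DNA replication, rose, and Aqp4 and Egr4 fell. Dscc1, Eme1, Tk1, Gmnn and Cks2, of cohesion, DNA repair, thymidine salvage, replication licensing and the cell cycle, rose by 0.75 ± 0.15, 0.66 ± 0.14, 0.65 ± 0.15, 0.63 ± 0.15 and 0.59 ± 0.13 (log2 fold change, SE, n = 12 against 12). Tk1 (ENSMUSG00000025574; chromosome 11, 117815526 to 117826092) rose from 13.3 ± 3.94 in Ctrl to 20.8 ± 3.02 in Both_0.3Cyp (normalised CPM, SD, n = 12 and 12) and lay above the Ctrl mean in 12 of 12 exposed libraries. Hmga2 rose by 0.89 ± 0.30 and the histone gene Hist2h2aa1 by 1.07 ± 0.40, beside Bcl2l12 (0.60 ± 0.13), Insm2 (0.61 ± 0.20) and Cpa4 (0.62 ± 0.23). Aqp4 fell (-1.08 ± 0.27), Egr4 (-1.03 ± 0.28), Nwd2 (-0.98 ± 0.23) and Ptk2b (-0.87 ± 0.21). Frmpd4, a postsynaptic scaffold protein, fell (-0.93 ± 0.17), and was lower than the Ctrl mean in 12 of 12 libraries, from 8.41 ± 2.72 in Ctrl to 4.39 ± 0.702 in Both_0.3Cyp (normalised CPM, SD, n = 12 and 12). Rasgrf2, a calcium-regulated exchange factor for Ras, fell (-0.92 ± 0.22) and Glra3, a glycine receptor subunit (-0.86 ± 0.28), beside Atp13a5 (-0.96 ± 0.23), Pakap (-0.95 ± 0.26) and Cpne7 (-0.88 ± 0.29). In all, 3202 genes differed from Ctrl, 1509 higher and 1693 lower, out of 14339 tested (edgeR quasi-likelihood). The named genes had adjusted p from 0.00264 to 0.0465 by edgeR quasi-likelihood; the median absolute log2 fold change of all genes that differed was 0.25, and 306 reached 0.5. The count was 0 within batch 1 (edgeR, 1944 at an unadjusted p under 0.05) and 1564 within batch 2, 10 with the globin ratio as a covariate, 0 by edgeR with 2 surrogate variables (1445 at an unadjusted p under 0.05; DESeq2 without them 3460), and 4807 with these groups fitted alone. All 20 named genes lost the call with that covariate. The count was 2042 without Ctrl replicate 3 and 2089 without Ctrl replicate 7.

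In embryos of fathers exposed at dose 10, Cks2 and Dscc1 rose by 0.61 ± 0.14 and 0.66 ± 0.16 and Neurod4 by 0.60 ± 0.15 (log2 fold change, SE, n = 10 against 12). Hist1h2ag rose by 0.84 ± 0.27 and Dusp14, a phosphatase of MAP kinases, by 0.61 ± 0.16, with Dusp14 above the Ctrl mean in 10 of 10 libraries. Scgn, a calcium-binding protein, rose by 0.63 ± 0.23 and Car14, a carbonic anhydrase, by 0.64 ± 0.20, beside Calml4 (0.81 ± 0.31), Kctd14 (0.73 ± 0.18) and Cox6b2 (0.63 ± 0.21). Rnf213 (ENSMUSG00000070327; chromosome 11, 119393100 to 119487418), a large ubiquitin ligase, fell (-1.07 ± 0.25), from 6.38 ± 2.63 in Ctrl to 2.99 ± 1.48 in Paternal_10Cyp (normalised CPM, SD, n = 12 and 10). Kcnk9, a leak potassium channel of neurons, fell (-0.87 ± 0.23) and was below the Ctrl mean in 10 of 10 libraries. Hspa1a, an inducible heat shock protein, fell (-0.82 ± 0.23), Egr4 (-0.92 ± 0.29), Nwd2 (-0.86 ± 0.25) and Slc25a18 (-0.89 ± 0.29). The other falling genes were Slc7a3 (-0.84 ± 0.29), a cationic amino acid transporter, Dchs2 (-0.84 ± 0.22), a cadherin, Ly75 (-0.85 ± 0.23), an endocytic receptor, and Fndc1 (-0.83 ± 0.22). In all, 3076 genes differed from Ctrl, 1533 higher and 1543 lower, out of 14339 tested (edgeR quasi-likelihood). The named genes had adjusted p from 0.00370 to 0.0470 by edgeR quasi-likelihood; the median absolute log2 fold change of all genes that differed was 0.24, and 229 reached 0.5. The count was 1 within batch 1 (edgeR, 1843 at an unadjusted p under 0.05) and 2674 within batch 2, 2289 with the globin ratio as a covariate, 158 with 2 surrogate variables, 1880 without the batch term, 1499 with GC and length offsets and 1770 without the libraries high in diencephalon markers. It was 1958 without Ctrl replicate 7 and 1794, 1709 and 1807 without Paternal_10Cyp replicates 2, 5 and 6.

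Among the 6 exposed groups, embryos of mothers exposed at dose 10 had the highest count of genes that differed from Ctrl, in the smallest group. Cks2 (ENSMUSG00000062248; chromosome 13, 51645232 to 51650660), which binds cyclin-dependent kinases, rose by 0.86 ± 0.14 (SE, n = 8 against 12), from 12.9 ± 3.99 in Ctrl to 23.6 ± 1.67 in Maternal_10Cyp (normalised CPM, SD, n = 12 and 8), and was above the Ctrl mean in 8 of 8 libraries. Hmgb2, a chromatin protein of dividing cells, rose by 0.84 ± 0.15, from 85.1 ± 28.3 in Ctrl to 152 ± 21.2 in Maternal_10Cyp (normalised CPM, SD, n = 12 and 8). Neurog1 rose by 1.57 ± 0.42, Hmga2 by 0.96 ± 0.33, Hist1h2ag by 1.05 ± 0.28 and Dmrta1, a transcription factor of cortical progenitors, by 0.91 ± 0.30. The remaining rising genes were Mafa (1.18 ± 0.48), Gcg (0.81 ± 0.15), Lrr1 (0.80 ± 0.17) and Mtfr2 (0.78 ± 0.15).

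The receptor genes Grin2a and Oprm1 fell in these embryos. Grin2a, an NMDA receptor subunit, fell (-1.18 ± 0.26), Oprm1, the mu opioid receptor (-1.18 ± 0.29) and Kctd16 (-1.38 ± 0.28). Rasgrf2 fell (-1.26 ± 0.25), Lrp1b, of the LDL receptor family (-1.26 ± 0.23) and Nwd2 (-1.37 ± 0.27), from 24.1 ± 8.80 in Ctrl to 9.21 ± 1.82 in Maternal_10Cyp (normalised CPM, SD, n = 12 and 8). Aqp4 fell (-1.21 ± 0.31), Thbs2, a secreted matrix glycoprotein (-1.25 ± 0.36), Rnf213 (-1.29 ± 0.28) and Fndc1 (-1.39 ± 0.25). In all, 5856 genes differed from Ctrl, 2929 higher and 2927 lower, out of 14339 tested (edgeR quasi-likelihood). The named genes had adjusted p from 6.81e-05 to 0.0428 by edgeR quasi-likelihood; the median absolute log2 fold change of all genes that differed was 0.29, and 996 reached 0.5. The count was 19 within batch 1 (edgeR, 3125 at an unadjusted p under 0.05) and 4762 within batch 2, 4023 with the globin ratio as a covariate, 448 with 2 surrogate variables, and stayed between 5056 and 6235 when any 1 library was left out.

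Where both parents were exposed at dose 10, genes of ribosomal proteins and the ATP synthase gene Atp5k were among the genes with the largest rises. The ribosomal protein genes Rps29, Rpl38, Rps28 and Rps21 rose by 0.71 ± 0.11, 0.68 ± 0.12, 0.66 ± 0.12 and 0.63 ± 0.11 (log2 fold change, SE, n = 10 against 12), and Rps29 was above the Ctrl mean in 10 of 10 libraries, from 93.7 ± 15.5 in Ctrl to 153 ± 19.98 in Both_10Cyp (normalised CPM, SD, n = 12 and 10). Atp5k, a subunit of ATP synthase, rose by 0.69 ± 0.12, and mt-Nd4l, a mitochondrially encoded subunit of complex I, by 0.81 ± 0.14. In contrast mt-Atp6, a mitochondrially encoded subunit of ATP synthase, fell (-0.81 ± 0.22), from 1454 ± 209.8 in Ctrl to 843 ± 496 in Both_10Cyp (normalised CPM, SD, n = 12 and 10). Libraries of Both_10Cyp were split in these 2 genes: 7 of 10 had a low ratio of mt-Atp6 to mt-Nd4l, with mt-Atp6 at 489 to 642 CPM, the others had 1354 to 1652, and 0 of 12 Ctrl libraries had the low ratio. Hmga2, Hist1h2ag and Dscc1 rose by 1.05 ± 0.31, 0.95 ± 0.26 and 0.60 ± 0.16, beside Smim27 (0.77 ± 0.19). Hmga2 was led by 2 libraries, with 8.92 and 7.63 CPM, and had 0.14 in batch 1 and 1.63 in batch 2. Sox10, a transcription factor of oligodendrocyte precursors, fell (-0.59 ± 0.18), Chrm4, a muscarinic acetylcholine receptor (-0.65 ± 0.16), and Vgf, a neuropeptide precursor (-0.64 ± 0.20). Rasgrf2 fell (-0.75 ± 0.22), Tenm2, a synaptic adhesion protein (-0.56 ± 0.16) and Csmd3 (-0.56 ± 0.17), beside Rnf213 (-0.90 ± 0.25), Atp13a5 (-0.92 ± 0.24) and Edn1 (-0.87 ± 0.27). In all, 561 genes differed from Ctrl, 335 higher and 226 lower, out of 14339 tested (edgeR quasi-likelihood). The named genes had adjusted p from 0.000123 to 0.0481 by edgeR quasi-likelihood; the median absolute log2 fold change of all genes that differed was 0.26, and 57 reached 0.5. The count was 0 within batch 1 (edgeR, 410 at an unadjusted p under 0.05) and 2642 within batch 2, 132 with the globin ratio as a covariate, 1085 by DESeq2, 952 by limma, 55 without the batch term, 342 with the replicate number as a block, 13 with 2 surrogate variables, 43 without the libraries high in embryonic globin, where 14 of the 20 named genes lost the call, and 283 without those high in diencephalon markers. It moved by more than 1.5 times for 14 of 22 libraries left out in turn: 190, 973, 1625, 63, 115, 257 and 147 without Ctrl replicates 3, 5, 6, 7, 8, 9 and 12, and 251, 1396, 1081, 915, 37, 29 and 935 without Both_10Cyp replicates 2, 3, 4, 6, 7, 8 and 10.

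**Figure D1:**
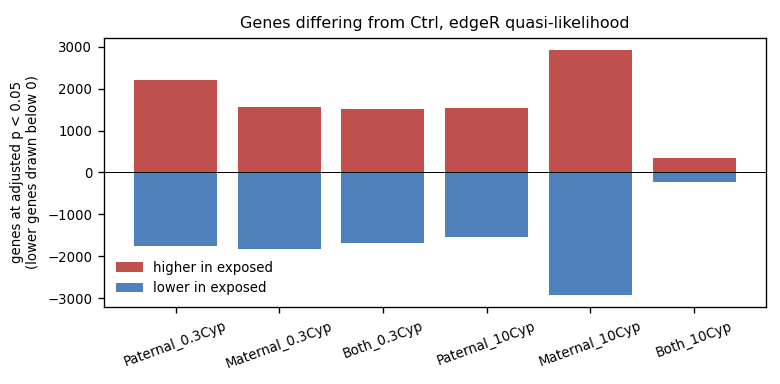
Bars give the number of genes higher (above 0) and lower (below 0) than Ctrl in each exposed group, at an adjusted p under 0.05 by edgeR quasi-likelihood. Maternal_10Cyp has 5856 genes and Both_10Cyp 561.

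**Figure D2:**
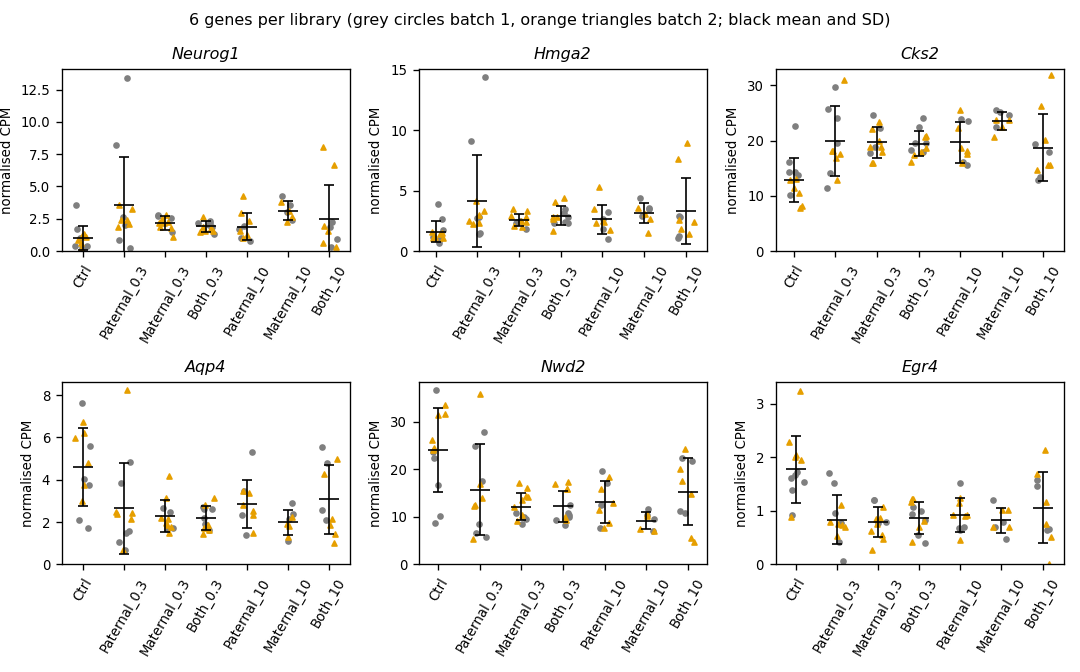
Normalised CPM of 6 named genes, 1 point per library, by group and batch, with the group mean and SD in black. Cks2 averages 12.9 in Ctrl and 23.6 in Maternal_10Cyp, and Nwd2 24.1 and 9.21.

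Described by gene lists, the exposed groups shared rises in progenitor, cell cycle, ribosomal and respiratory genes. Of the markers of intermediate progenitors, the cells that divide to give cortical neurons, 11 of 12 rose in Maternal_10Cyp (12 adjusted over the list alone) and 3 to 12 in each of the other 5 exposed groups. Among them were Mfng (0.63 ± 0.14), Gadd45g (0.65 ± 0.15), Sstr2 (0.47 ± 0.12) and Rhbdl3 (0.69 ± 0.18) (log2 fold change, SE, n = 8 against 12). Among cell cycle genes 31 of 37 rose in Maternal_10Cyp and 2 to 33 elsewhere. Among them were Pcna (0.46 ± 0.094), the replication clamp, and the mitotic genes Ccnb2 (0.64 ± 0.14) and Cdk1 (0.60 ± 0.14). Cytosolic ribosomal protein genes rose for 73 of 79 (75 adjusted over the list alone) and 18 to 66 elsewhere. Among them were Rps28 (0.69 ± 0.12), Rps29 (0.66 ± 0.12), Rps27l (0.61 ± 0.11) and Rpl23 (0.41 ± 0.079). Nuclear-encoded genes of oxidative phosphorylation rose for 61 of 69 (63 adjusted over the list alone) and 9 to 56 elsewhere. Among them were Ndufa6 (0.48 ± 0.087), Atp5j (0.39 ± 0.073), Atp5k (0.67 ± 0.13) and Cox7c (0.49 ± 0.10). Camera with its preset correlation called these 4 lists upward in all 6 exposed groups. In Maternal_10Cyp the intermediate progenitor list had camera adjusted p = 3.47e-06, adjusted p = 0.371 with an estimated correlation. The cell cycle list had camera adjusted p = 1.24e-11, adjusted p = 0.399 with an estimated correlation. The ribosomal list had camera adjusted p = 3.20e-22, adjusted p = 0.371 with an estimated correlation. The oxidative phosphorylation list had camera adjusted p = 3.27e-19, adjusted p = 0.371 with an estimated correlation. With GC and length offsets the medians of the ribosomal list, 0.18 to 0.30 over the 6 groups, were 0.061 to 0.11, and those of the oxidative phosphorylation list 0.016 to 0.060 in place of 0.12 to 0.28. In each exposed group, camera with correlations estimated per list called 0 of 41 lists. The counts were 23, 23, 21, 24, 17 and 23 with the preset value and 23, 20, 22, 21, 23 and 19 by fry, in the order Paternal_0.3Cyp, Maternal_0.3Cyp, Both_0.3Cyp, Paternal_10Cyp, Maternal_10Cyp and Both_10Cyp.

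Genes of synapses and excitability fell, and camera called each of the lists that follow downward in all 6 exposed groups with its preset correlation. In Maternal_10Cyp 20 of 24 glutamate receptor and transporter genes fell (21 adjusted over the list alone), and 3 to 17 in the other exposed groups. Among them were Grik2 (-0.47 ± 0.080), Gria2 (-0.63 ± 0.13), Gria3 (-0.44 ± 0.086) and Grm7 (-0.98 ± 0.20). The glutamate list had camera adjusted p = 1.72e-09, adjusted p = 0.371 with an estimated correlation. Of synaptic vesicle and postsynaptic genes 22 of 27 fell (23 adjusted over the list alone), 3 to 23 elsewhere. Among them were the adhesion gene Nlgn3 (-0.39 ± 0.063), the scaffold Shank2 (-0.50 ± 0.11) and the vesicle protein Syn2 (-0.48 ± 0.11). The synaptic list had camera adjusted p = 5.59e-10, adjusted p = 0.371 with an estimated correlation. GABA signalling genes fell for 15 of 19 and 1 to 14 elsewhere. Among them were the receptor subunits Gabrb1 (-0.91 ± 0.19) and Gabbr2 (-0.71 ± 0.17). The GABA list had camera adjusted p = 6.77e-06, adjusted p = 0.399 with an estimated correlation. Sodium channels, the target of pyrethroids in neurons, fell for 7 of 10 (9 adjusted over the list alone) and 0 to 8 elsewhere. Among them were Scn2a (-0.70 ± 0.16), Scn8a (-0.46 ± 0.10), Scn9a (-0.93 ± 0.23) and Nalcn (-0.69 ± 0.16). The sodium channel list had camera adjusted p = 0.000700, adjusted p = 0.371 with an estimated correlation. Of voltage-gated calcium channel genes 11 of 15 fell, 0 to 10 elsewhere. Among them were Cacna1a (-0.55 ± 0.11), Cacna1d (-0.52 ± 0.11), Cacna1g (-0.55 ± 0.11) and Cacna1i (-0.70 ± 0.15). The calcium channel list had camera adjusted p = 6.77e-06, adjusted p = 0.371 with an estimated correlation. Of 62 genes with known ties to autism, 36 fell and 1 rose in Maternal_10Cyp (38 and 1 adjusted over the list alone), and 4 to 26 fell elsewhere. Among them were Ank2 (-0.65 ± 0.13) and Foxp1 (-0.50 ± 0.10) beside Nlgn3. The autism list had camera adjusted p = 1.28e-09, adjusted p = 0.371 with an estimated correlation, and with GC and length offsets camera called it in 2 of 6 groups (on ranked statistics). Of the autism genes 20 are on another list, 11 of them on a synaptic, receptor or channel list. Monoamine and acetylcholine signalling genes fell for 13 of 29 and 2 to 11 elsewhere. Among them were the receptors Chrm1 (-0.67 ± 0.16), Chrm2 (-0.58 ± 0.16), Chrm4 (-0.82 ± 0.18) and Htr1a (-0.77 ± 0.21). The monoamine and acetylcholine list had camera adjusted p = 0.00205, adjusted p = 0.418 with an estimated correlation.

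Glial markers and genes of cholesterol synthesis and the circadian clock fell as well, each list called downward by camera in all 6 exposed groups. Oligodendrocyte precursor markers fell for 7 of 8 in Maternal_10Cyp and 1 to 6 elsewhere. Among them were Cspg4 (-0.9995 ± 0.17), Pdgfra (-0.74 ± 0.16), Sox10 (-0.74 ± 0.20) and Gpr17 (-0.67 ± 0.20). The precursor list had camera adjusted p = 0.000812, adjusted p = 0.371 with an estimated correlation. Early astrocyte markers fell for 8 of 11 and 0 to 5 elsewhere. Among them were Sparcl1 (-0.57 ± 0.12), Bcan (-0.44 ± 0.11) and Slc1a2 (-0.46 ± 0.12). The astrocyte list had camera adjusted p = 0.00883, adjusted p = 0.371 with an estimated correlation. Striatal neuron markers fell for 6 of 15 and 1 to 7 elsewhere. Among them were the dopamine receptors Drd1 (-0.35 ± 0.13) and Drd2 (-0.54 ± 0.15) and the opioid precursor Penk (-0.64 ± 0.20). The striatal list had camera adjusted p = 0.0473, adjusted p = 0.497 with an estimated correlation. Cholesterol synthesis genes fell for 14 of 20 (15 adjusted over the list alone) and 5 to 13 elsewhere. Among them were Hmgcs1 (-0.38 ± 0.080), Dhcr7 (-0.28 ± 0.048) and Lss (-0.28 ± 0.074). The cholesterol list had camera adjusted p = 1.94e-05, adjusted p = 0.371 with an estimated correlation. Circadian clock genes fell for 7 of 19 (8 adjusted over the list alone) and 2 to 6 elsewhere. Among them were Per1 (-0.43 ± 0.085), Cry2 (-0.29 ± 0.054), Bhlhe40 (-0.50 ± 0.10) and Nr1d1 (-0.26 ± 0.083). The clock list had camera adjusted p = 0.00407, adjusted p = 0.371 with an estimated correlation.

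For genes of the glucocorticoid and stress axis, 10 of 23 fell and 2 rose in Maternal_10Cyp. The mineralocorticoid receptor gene Nr3c2 fell (-0.94 ± 0.21), as did the hormone-responsive factor Klf9 (-0.69 ± 0.17), while the cochaperone Fkbp4 (0.24 ± 0.055) rose. Camera called the list downward in 5 exposed groups (smallest adjusted p = 0.290 with an estimated correlation), not in Maternal_10Cyp (adjusted p = 0.0835). Of immediate early genes 8 of 22 fell, with Egr3 (-0.73 ± 0.13), Nr4a2 (-0.56 ± 0.11) and Nr4a3 (-0.57 ± 0.13), and 4 rose, with Btg2 (0.55 ± 0.12) (9 and 4 adjusted over the list alone). The immediate early list was called downward in 5 exposed groups by camera (smallest adjusted p = 0.290 with an estimated correlation). Interferon response genes fell for 10 of 23, with Stat2 (-0.29 ± 0.075), Irf9 (-0.32 ± 0.10) and Ddx58 (-0.55 ± 0.18). The interferon list was called downward in 5 exposed groups by camera (smallest adjusted p = 0.307 with an estimated correlation). In hypoxia and glycolysis 8 of 20 fell and 2 rose. Falling were Slc2a3 (-0.47 ± 0.093), Hk1 (-0.40 ± 0.084), Pfkp (-0.85 ± 0.22) and Vegfa (-0.60 ± 0.14). The hypoxia list was called downward in 4 exposed groups by camera (smallest adjusted p = 0.303 with an estimated correlation). Oxidative stress genes rose for 8 of 25 and fell for 2. Rising were Prdx1 (0.31 ± 0.080), Prdx2 (0.31 ± 0.076), Sod1 (0.27 ± 0.075) and Gpx4 (0.25 ± 0.076). The oxidative stress list was called upward in 3 exposed groups by camera (smallest adjusted p = 0.394 with an estimated correlation), none of them with GC and length offsets (medians 0.022 to 0.045). Erythroid markers rose for 7 of 10 in Paternal_0.3Cyp (8 adjusted over the list alone), with the embryonic Hba-x (2.81 ± 0.67) and the adult Hbb-bt (0.43 ± 0.11) and Hba-a2 (0.40 ± 0.10). Hba-x stood at -0.078 with the globin covariate, which is built in part from Hba-x and so does not test its rise. The erythroid list was called upward in 5 exposed groups by camera (smallest adjusted p = 0.290 with an estimated correlation), in 3 with the offsets, and in Maternal_10Cyp 0 passed. Diencephalon markers rose for 8 of 14 in Paternal_0.3Cyp (9 adjusted over the list alone), with Pou4f1 (2.38 ± 0.66) and Lhx9 (0.77 ± 0.25). The diencephalon list was called upward in 1 exposed group by camera (smallest adjusted p = 0.479 with an estimated correlation). In Maternal_10Cyp Lhx2 (0.38 ± 0.12) rose and Foxb1 (-2.06 ± 0.66) and Sim1 (-1.64 ± 0.65) fell on that list. The share of the diencephalon markers rose from 0.0306 ± 0.00419 percent of counts in Ctrl to 0.0370 ± 0.00259 in Maternal_10Cyp (SD, n = 12 and 8). Differences were 0.00459 in batch 1 and 0.00820 in batch 2 (adjusted p = 0.0117, exact permutation test). By the same test it rose in Paternal_0.3Cyp, Maternal_0.3Cyp and Both_0.3Cyp (adjusted p = 0.0141, 0.0188 and 0.0142). It did not pass in Paternal_10Cyp or Both_10Cyp (adjusted p = 0.0751 and 0.391). A summed share weighs abundant members most and need not show more diencephalic tissue.

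Other lists moved in few groups or in none. Camera called choroid plexus markers upward in 2 exposed groups (smallest adjusted p = 0.460 with an estimated correlation) and microglia and macrophage markers upward in 1 exposed group (smallest adjusted p = 0.510 with an estimated correlation). It called upper-layer neuron markers downward in 2 exposed groups (smallest adjusted p = 0.328 with an estimated correlation). With GC and length offsets the upper-layer and microglia lists were called in none, and upper-layer medians ran from -0.033 to 0.11. Pericyte and smooth muscle markers were called downward in 1 exposed group (smallest adjusted p = 0.494 with an estimated correlation) and thyroid hormone response genes downward in 1 exposed group (smallest adjusted p = 0.290 with an estimated correlation). In Maternal_10Cyp 0 members rose and 0 fell of 15 for choroid plexus and 0 and 0 of 16 for microglia. Upper-layer neurons had 0 and 3 of 13 and pericytes 0 and 3 of 11. Thyroid hormone response had 1 and 5 of 15 (1 and 6 adjusted over the list alone). The other 13 lists were called in none of the exposed groups by camera. On ranked statistics, the offsets took the groups called from 1 to 4 for mitochondrially encoded mRNAs (medians -0.20 to -0.065 with them). They took them from 1 to 2 for cortical hem and 0 to 1 for interneurons and pericytes. Among DNA methylation and chromatin regulators 7 and 15 of 45 rose and fell in Maternal_10Cyp. The members went both ways: Mbd3 (0.33 ± 0.063), Hdac1 (0.41 ± 0.089) and Hdac2 (0.25 ± 0.052) rose and Ezh1 (-0.31 ± 0.064) fell. Imprinted genes, which are read from 1 parental allele, rose and fell for 5 and 9 of 36. The imprinted gene Mest (0.41 ± 0.086) rose, and Igf2r (-0.58 ± 0.14), Zim1 (-0.71 ± 0.19) and Peg3 (-0.58 ± 0.16) fell. Radial glia markers rose and fell for 7 and 3 of 19 (8 and 3 adjusted over the list alone). There Hes1 (0.69 ± 0.14) and Dbi (0.53 ± 0.11) rose, while Tnc (-0.87 ± 0.17) and Ptprz1 (-0.59 ± 0.12) fell. Xenobiotic metabolism genes rose and fell for 0 and 6 of 19. The aryl hydrocarbon receptor gene Ahr (-0.59 ± 0.17) and the transporter gene Abcb1a (-0.57 ± 0.15) fell. Deep-layer neuron markers had 0 and 4 of 13 (0 and 4 adjusted over the list alone), with Tle4 (-0.22 ± 0.057), Foxp2 (-0.26 ± 0.10) and Bcl11b (-0.23 ± 0.086). Interneuron markers had 1 and 4 of 21 (1 and 4 adjusted over the list alone), with Gad1 (-0.52 ± 0.15) and Erbb4 (-0.46 ± 0.12). Cajal-Retzius markers had 0 and 3 of 10 (0 and 3 adjusted over the list alone), with Reln (-0.70 ± 0.19). Endothelial markers had 0 and 2 of 14 (0 and 2 adjusted over the list alone), with Flt1 (-0.66 ± 0.14) and Kdr (-0.49 ± 0.13). For cortical hem and hippocampus the counts were 2 and 3 of 14 (2 and 3 adjusted over the list alone), with Dmrta2 (0.61 ± 0.17) rising and Prox1 (-0.52 ± 0.14) and Zbtb20 (-0.53 ± 0.15) falling. They were 0 and 0 of 15 (0 and 0 adjusted over the list alone) for meninges and 2 and 3 of 11 (2 and 3 adjusted over the list alone) for heat shock proteins, with Hspe1 (0.34 ± 0.075) rising. Counts for the unfolded protein response were 5 and 1 of 18 (5 and 1 adjusted over the list alone), with Psat1 (0.35 ± 0.089) rising, and 2 and 0 of 13 (2 and 0 adjusted over the list alone) for mitochondrially encoded mRNAs, with mt-Atp8 (0.51 ± 0.11) rising. In Maternal_10Cyp the median and the mean log2 fold change differed in sign for interneuron (0.046 and -0.031) and microglia markers (0.022 and -0.013). Both were opposite to the direction of camera for cortical hem and hippocampus (5.38e-04 and 0.034, camera adjusted p = 0.930) and heat shock proteins (-0.0033 and -0.15, camera adjusted p = 0.984). In other groups such signs differed only for lists that camera did not call there: heat shock, imprinted, interferon, xenobiotic, mitochondrially encoded, unfolded protein, pericyte, endothelial, meningeal and diencephalon genes. With 2 surrogate variables the fold changes in Maternal_10Cyp turned sign for Lhx2 (-0.024), Zim1 (0.017), Gad1 (0.057), Gpr17 (0.10) and Penk (0.071), and with GC and length offsets for Bcl11b (0.015).

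**Figure D3:**
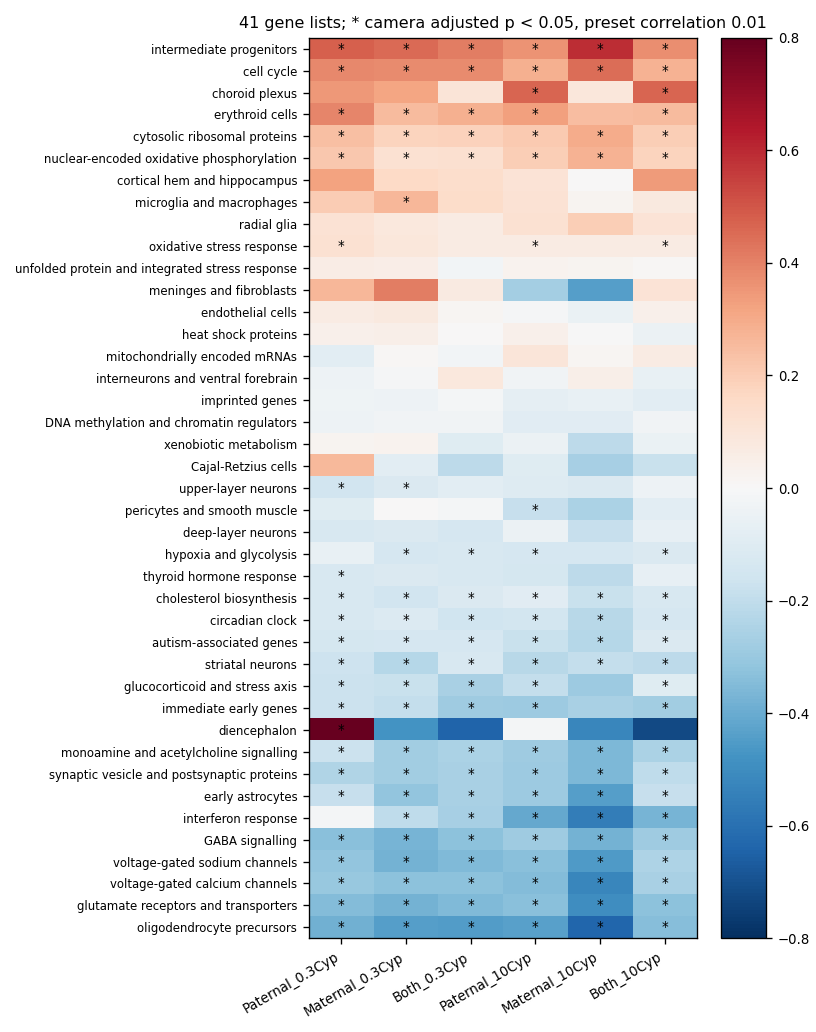
Each cell shows the median log2 fold change (exposed minus Ctrl) of the measured members of a gene list, in columns for the 6 exposed groups, and a star marks an adjusted p under 0.05 by camera with its preset correlation. In Maternal_10Cyp the medians run from -0.64 for oligodendrocyte precursors to 0.59 for intermediate progenitors.

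The shares of all counts taken by the gene lists were compared with those in Ctrl. The ribosomal protein share rose in all 6 exposed groups, from 3.10 ± 0.308 percent of counts in Ctrl to 3.53 ± 0.211 in Both_0.3Cyp (SD, n = 12 and 12) with differences of 0.467 in batch 1 and 0.402 in batch 2 (adjusted p = 0.000323, exact permutation test). In the other groups its adjusted p was 0.0275 in Paternal_0.3Cyp, 0.0115 in Maternal_0.3Cyp, 0.0156 in Paternal_10Cyp, 0.00156 in Maternal_10Cyp and 0.0117 in Both_10Cyp (exact permutation test within batches). The intermediate progenitor share rose in Maternal_10Cyp, from 0.0730 ± 0.0155 percent of counts in Ctrl to 0.101 ± 0.00561 in Maternal_10Cyp (SD, n = 12 and 8). The differences were 0.0253 in batch 1 and 0.0297 in batch 2 (adjusted p = 0.0115, exact permutation test), and the share also rose in Paternal_0.3Cyp, Maternal_0.3Cyp and Both_0.3Cyp, but did not pass in Paternal_10Cyp (adjusted p = 0.0607, exact permutation test) or Both_10Cyp (adjusted p = 0.147). The oligodendrocyte precursor share fell in Maternal_10Cyp, from 0.0203 ± 0.00468 percent of counts in Ctrl to 0.0139 ± 0.00116 in Maternal_10Cyp (SD, n = 12 and 8). Its differences were -0.00577 in batch 1 and -0.00717 in batch 2 (adjusted p = 0.0152, exact permutation test), and it also fell in Maternal_0.3Cyp, Both_0.3Cyp and Paternal_10Cyp, not past the threshold in Paternal_0.3Cyp (adjusted p = 0.124, exact permutation test) or Both_10Cyp (adjusted p = 0.174). Early astrocyte markers fell in Both_0.3Cyp, Paternal_10Cyp and Maternal_10Cyp, the last with differences of -0.0118 in batch 1 and -0.0174 in batch 2 percentage points (adjusted p = 0.0156, exact permutation test). They did not pass in Paternal_0.3Cyp, Maternal_0.3Cyp or Both_10Cyp (adjusted p = 0.251, 0.0823 and 0.241, exact permutation test). The radial glia share rose in Maternal_0.3Cyp (adjusted p = 0.0167, exact permutation test), although camera called that list in none of the groups. The log2 ratio of embryonic to adult globin counts, which falls as red cells of the yolk sac are replaced, was higher in Maternal_10Cyp. It rose from -12.6 ± 1.65 in Ctrl to -10.5 ± 0.557 in Maternal_10Cyp (SD, n = 12 and 8; adjusted p = 0.0188, exact permutation test). That ratio also rose in Maternal_0.3Cyp, to -10.9 ± 0.621, and in Both_0.3Cyp, to -10.9 ± 0.902 (SD, n = 12 and 12, adjusted p = 0.0188 and 0.0227, exact permutation test). It did not pass in Paternal_0.3Cyp, Paternal_10Cyp or Both_10Cyp (adjusted p = 0.0613, 0.174 and 0.522, exact permutation test). In Both_10Cyp the differences were -0.296 in batch 1 and 1.80 in batch 2. Most ratios rest on few embryonic globin counts, 0 to 26 per Ctrl library. With 0, the added 0.5 sets the ratio of Ctrl replicate 2 (-16.1) and Both_10Cyp replicate 3 (-16.7, batch 1). Erythroid and adult globin shares rose in Paternal_0.3Cyp, Both_0.3Cyp and Paternal_10Cyp (erythroid adjusted p = 0.0356, 0.0241 and 0.0188, exact permutation test), and embryonic globin rose in Maternal_0.3Cyp, Both_0.3Cyp and Maternal_10Cyp. The striatal share fell in Paternal_0.3Cyp, Maternal_0.3Cyp and Paternal_10Cyp (adjusted p = 0.0188, 0.0160 and 0.0351, exact permutation test). In Maternal_10Cyp the Cajal-Retzius share fell (adjusted p = 0.0141, exact permutation test), and the 100 most abundant genes rose from 17.3 ± 0.442 percent of counts in Ctrl to 17.9 ± 0.421 in Maternal_10Cyp (SD, n = 12 and 8) (adjusted p = 0.0188). Of 138 such 2-sided tests over 23 measures, 39 passed.

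**Figure D4:**
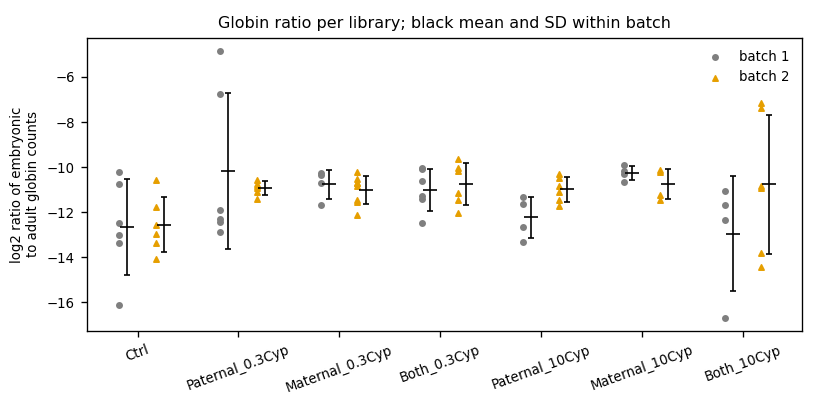
Each point is a library's log2 ratio of embryonic to adult globin counts, by group and batch, with the mean and SD within batch in black. Batch means of Ctrl are -12.7 and -12.6, and those of Maternal_10Cyp -10.3 and -10.8.

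Genes that differed from Ctrl in more than 1 exposed group did so in the same direction. Higher than Ctrl in all 6 groups were 218 genes and lower 159, of 7051 genes that differed in at least 1, and 0 genes differed in opposite directions in any pair of groups by edgeR. The counts for all 6 are limited by Both_10Cyp, whose 561 calls fell to 29, 37 and 63 without its replicate 8, its replicate 7 or Ctrl replicate 7, and over the other 5 groups 708 were higher and 763 lower. With 2 surrogate variables edgeR called 0 genes in each group at dose 0.3 (1592, 1070 and 1445 at an unadjusted p under 0.05), so that none were shared by all. The 6 comparisons use the same Ctrl libraries, which alone makes their fold changes alike. Across 14339 genes, which are not independent replicates, the correlation of log2 fold changes ran from r = 0.674 (Paternal_0.3Cyp with Paternal_10Cyp) to 0.850 (Maternal_0.3Cyp with Both_0.3Cyp) over 15 pairs. In 20 simulations with no group difference the means per pair started at 0.433 and the highest single value was 0.603. Genes were drawn independently there, so these values show the effect of the shared Ctrl libraries only. They give no upper limit for chance among real genes, which vary together. For the pair with the highest r, 1066 genes rose and 1310 fell in both, against 165 and 217 for independent lists, and the covariance was 0.0485 against 0.0137 simulated. For the pair with the lowest r, 1049 rose and 953 fell in both, against 236 and 189, and the covariance was 0.0430 against 0.0142. The values for independent lists leave out the shared Ctrl libraries, and the simulations call too few genes to give a chance value for these overlaps. With batch 1 of 1 group set against batch 2 of the other, so that no library is shared, r ran from -0.0143 to 0.597, with a median of 0.364. Within 1 exposed group, batch 1 against batch 2 gave r = 0.327 for Paternal_0.3Cyp, 0.418 for Maternal_0.3Cyp, 0.351 for Both_0.3Cyp, 0.373 for Paternal_10Cyp, 0.567 for Maternal_10Cyp and 0.161 for Both_10Cyp. By the joint test, 3106 genes differed among the groups in any exposure (edgeR quasi-likelihood).

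To ask what the dose changed, dose 10 was compared with dose 0.3 for each parental route. Between the paternal groups 9 genes differed, each higher at dose 10: Dcun1d1 (0.19 ± 0.036), Tmed7 (0.14 ± 0.029), Vps35 (0.13 ± 0.027), Ssr3 (0.13 ± 0.028), Exoc5 (0.16 ± 0.034), Kpna3 (0.14 ± 0.032), Btbd1 (0.13 ± 0.028), Ei24 (0.13 ± 0.029) and Cfl2 (0.15 ± 0.033) (log2 fold change, SE, n = 10 against 12). By edgeR quasi-likelihood their adjusted p ran from 0.0253 to 0.0466. Vps35, of the retromer, Tmed7, Ssr3 and Exoc5 act in membrane traffic and secretion, and Cfl2 is a cofilin. The last 4 genes of the list were named after their values were seen. The count was 58 by DESeq2, 206 by limma, 0 in batch 1 alone (2051 at an unadjusted p under 0.05) and 1 in batch 2 alone. By edgeR it was 0 with only the groups compared and 0 without the libraries high in diencephalon markers (583 and 998 at an unadjusted p under 0.05), 2 with GC and length offsets, 2 without the batch term and 3 without the libraries high in embryonic globin. Between the maternal groups 0 genes differed by edgeR (1291 at an unadjusted p under 0.05; DESeq2 6, limma 436). The genes of lowest p were Dock8 (-0.86 ± 0.17), Vapa (0.24 ± 0.056), Timm29 (0.13 ± 0.030), mt-Atp8 (0.46 ± 0.11) and Crybg3 (-0.49 ± 0.12), with edgeR quasi-likelihood adjusted p from 0.0633 to 0.225. Where both parents were exposed, mt-Nd4l alone differed, higher at dose 10 by 0.71 ± 0.14 (edgeR quasi-likelihood adjusted p = 0.0245). It averaged 65.1 ± 11.03 CPM in Both_0.3Cyp and 104 ± 21.3 in Both_10Cyp (SD, n = 12 and 10). The call was lost with GC and length offsets, in each batch alone, without the batch term, with the replicate number as a block and without the libraries high in embryonic globin. Over all 15 other settings the difference ran from 0.47 to 0.86 and its adjusted p from 0.000384 to 0.855 by edgeR, DESeq2 or limma. The next genes were Nucks1 (0.21 ± 0.046), Mcc (0.58 ± 0.14), Cd47 (0.21 ± 0.057) and Tmem50b (0.12 ± 0.034), which did not pass.

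The parent exposed was compared at each dose. At dose 0.3, Irx2, a patterning transcription factor near the detection limit (0.843 CPM over all libraries, named after its value was seen), was lower in Maternal_0.3Cyp than in Paternal_0.3Cyp (log2 fold change -3.57 ± 0.71, edgeR quasi-likelihood adjusted p = 0.0459). Irx1, Mab21l2, Hbb-y and Prph were the next in that direction, with log2 fold changes of -2.11 ± 0.45, -2.001 ± 0.49, -3.28 ± 0.81 and -0.94 ± 0.22, and did not pass. Nor did Ttll11 (-0.32 ± 0.079). Without the libraries high in embryonic globin Hbb-y had 0.013. The call of Irx2 is lost in each of the 2 batches alone (0 genes in batch 1 and 0 in batch 2 by edgeR, 300 and 1059 at an unadjusted p under 0.05). The count was also 0 by limma, with only the groups compared and with the replicate number as a block (886, 265 and 933 at an unadjusted p under 0.05). By edgeR it was 0 without the libraries high in diencephalon markers, with GC and length offsets and in thinned counts (597, 483 and 574). At dose 10, 0 genes differed between the maternal and the paternal group by edgeR (718 at an unadjusted p under 0.05; DESeq2 2, limma 0). Among the lowest in p were Orc3 (-0.14 ± 0.036), Washc1 (0.23 ± 0.060) and Zbtb14 (0.17 ± 0.046), none past the threshold.

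Whether the effects of the parents add up was tested as the group with both exposed minus the sum of the maternal and the paternal effect. At dose 10, 3904 genes departed from the sum, 2001 upward and 1903 downward (edgeR quasi-likelihood). Nlgn3, a synaptic adhesion gene, had a departure of 0.57 ± 0.088, and Cacng8, an auxiliary subunit of AMPA receptors, of 0.52 ± 0.092, beside Camta2 (0.55 ± 0.093), Golga7 (-0.32 ± 0.057) and Mcc (1.19 ± 0.21). All 3904 departures were opposite in sign to the mean of the maternal and paternal effects, a relation to which the shared Ctrl libraries and the choice of these genes contribute. For 3805 Both_10Cyp lay between Ctrl and the sum. Over all 14339 genes the median absolute log2 fold change was 0.11 in Both_10Cyp, 0.17 in Maternal_10Cyp and 0.13 in Paternal_10Cyp. The count was 322 with 2 surrogate variables, 494 in batch 1 alone and 553 in batch 2 alone, and 6124 by limma. At dose 0.3, 0 genes departed by edgeR (3659 at an unadjusted p under 0.05; DESeq2 410, limma 773). There Scmh1 (0.30 ± 0.060), Klf5 (0.79 ± 0.17), Clp1 (-0.52 ± 0.12), Fgf14 (0.44 ± 0.10) and Nr4a1 (0.76 ± 0.17) had the lowest p, with edgeR quasi-likelihood adjusted p from 0.0510 to 0.0756. Whether the 2 doses differ in this was not tested.

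Male and female embryos differed in 13 genes, most of them on the sex chromosomes. The Y-linked genes Kdm5d, Ddx3y, Uty and Eif2s3y averaged 26.8 ± 2.96, 34.03 ± 2.78, 12.5 ± 1.79 and 20.4 ± 3.09 CPM in males (SD, n = 40) and at most 0.0229 in females, and Uba1y was called with them. The X-linked genes Eif2s3x (-0.56 ± 0.018), Kdm6a (-0.58 ± 0.041), Kdm5c (-0.46 ± 0.045), Ddx3x (-0.18 ± 0.027) and Pbdc1 (-0.27 ± 0.045), which include known escapees of X inactivation, were lower in males (log2 fold change, SE, n = 40 against 36). Outside the sex chromosomes Klk8 (0.37 ± 0.080) was higher and Pcdha8 (-0.79 ± 0.17) lower in males, and 1 further call is a predicted gene. A response to exposure that differed by sex was found for 0 genes in the joint test by edgeR (367 at an unadjusted p under 0.05; DESeq2 2, limma 0). Ddx3y, Eif2s3y, Plod2, Tecpr1 and Calb2 had the lowest p. In single groups 1 gene passed, Aldh1a1 in Paternal_0.3Cyp, with a log2 fold change of -3.14 in females and 2.75 in males (edgeR quasi-likelihood adjusted p = 0.0107, 0.503 CPM over all libraries). Responses that differed by batch were found for 0 genes in the joint test by edgeR (950 at an unadjusted p under 0.05; DESeq2 5, limma 84), with Mtpap, Vegfa, P4ha1, Med25 and Adm at the lowest p. Mtpap, the mitochondrial poly(A) polymerase, was called for Paternal_10Cyp, with log2 fold changes of -0.26 in batch 1 and 0.10 in batch 2 (edgeR quasi-likelihood adjusted p = 0.0145).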

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

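The tests against other splits, the globin covariate, the globin slopes, thinning, the GC and length offsets, the mt-Atp6 covariate, the contrast without Ctrl and the removal of libraries were chosen after the gene counts were seen. In groups of at most 10 libraries, 1 library lay far from the rest in 5 of 132 sets of values, where chance alone gives 6.60. Paternal_10Cyp replicate 4 had an oligodendrocyte precursor share of 0.0222 against 0.0129 to 0.0170 percent of counts. In Maternal_10Cyp, replicate 6 had an early astrocyte share of 0.0567 against 0.0428 to 0.0488 percent and replicate 2 an interneuron share of 0.174 against 0.142 to 0.153 percent. Replicate 1 of that group had a ribosomal protein share of 4.39 against 3.44 to 3.86 percent, and its 100 most abundant genes took 18.8 against 17.5 to 18.03 percent. Groups of 12 were not examined this way and hold such libraries too. In Paternal_0.3Cyp, replicate 8 had a ribosomal protein share of 6.06 against at most 3.98 percent and 20.53 against at most 18.1 percent of counts in its 100 most abundant genes, and replicate 4 an embryonic globin share of 0.00815 against at most 0.00212 percent.

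Tests of a difference between exposed groups gave 9 genes for dose among the paternal groups (Dcun1d1, Tmed7, Vps35, Ssr3, Exoc5, Kpna3, Btbd1, Ei24 and Cfl2), 1 for dose where both parents were exposed (mt-Nd4l) and 1 for mother against father at dose 0.3 (Irx2). There were 3904 for non-additivity at dose 10. A response that differed by sex was called for 1 gene, Aldh1a1 in Paternal_0.3Cyp, and 1 that differed by batch for 1 gene, Mtpap in Paternal_10Cyp.

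Each count was set against 100 splits of the same libraries into groups of the same sizes, the real one included. Chance placing of single embryos is argued against, though not excluded, for Paternal_0.3Cyp (3961 against at most 13 genes in another split), Maternal_0.3Cyp (3404 against at most 675) and Both_0.3Cyp (3202 against at most 1531). The same holds for Paternal_10Cyp (3076 against at most 947), Maternal_10Cyp (5856 against at most 960), any exposure (3106 against at most 2291) and non-additivity at dose 10 (3904 against at most 2594). For these 7 counts 1 of 100 splits, the real one, gave as many genes. For Both_10Cyp 2 of 100 did, and the highest other split gave 1486 genes where the real one gave 561. For dose among paternal groups 3 of 100 did (9 against at most 17) and for male against female 2 of 100 (13 against at most 2605). It cannot be excluded for dose where both parents were exposed (9 of 100, 1 against at most 559) and for mother against father at dose 0.3 (8 of 100, 1 against at most 2857). Where edgeR called 0 genes all 100 splits gave as many: the highest other split had 3742 for dose among maternal groups (1291 at an unadjusted p under 0.05) and 5 for mother against father at dose 10 (718). It had 2 for non-additivity at dose 0.3 (3659), 5 for sex by exposure (367) and 3 for batch by exposure (950). Splits that call many genes where the real comparison calls few point to a structure of the samples that the labels do not give, whose source was not tested. The splits move single embryos, so a chance spread of whole litters over the groups is not excluded.

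Each exposed group differed from Ctrl in the same direction, toward progenitor, cell cycle and ribosomal genes and away from synaptic and glial ones by camera with its preset correlation, while with an estimated correlation camera called 0 of 41 lists in each group (smallest adjusted p = 0.290). Depth is argued against as the whole cause, but not a separate deep run: over the 6 groups the calls summed to 20060, and to 19579 in thinned counts. The 5 libraries high in diencephalon markers are argued against as the whole cause, since the sum was 15221 without them. Their removal cannot test a smaller difference in tissue shared by most libraries of a group, which stays open. GC content and transcript length are argued against as the whole cause but not as a part: with offsets the sum was 14930 (Paternal_10Cyp 1499, the joint test 1928 for 3106), and camera on ranked edgeR statistics made 118 of 133 calls of lists again, while medians per group were 0.18 to 0.30 without and 0.061 to 0.11 with them for ribosomal genes, 0.12 to 0.28 without and 0.016 to 0.060 with them for oxidative phosphorylation and -0.23 to -0.12 without and -0.043 to -0.011 with them for autism genes. A difference in developmental stage, with Ctrl embryos older, stays open and may account for part of the pattern: with the embryonic to adult globin ratio as a covariate the sum was 6668, and across 14339 genes (not independent replicates) slopes on that ratio among the 64 exposed libraries correlated with the mean log2 fold change (r = 0.679, 0.649 without the 2 farthest libraries, at most 0.647 in 100 shufflings). The ratio rests on few counts in most libraries and did not pass in Paternal_0.3Cyp, Paternal_10Cyp and Both_10Cyp (adjusted p = 0.0613, 0.174 and 0.522, exact permutation test). Stage, litter and exposure cannot be separated without litter labels. A slower development caused by the exposure of a parent, which the design names, remains an untested possibility.

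The mitochondrial gene mt-Nd4l was higher in Both_10Cyp than in Both_0.3Cyp, by 0.71 ± 0.14 (SE, edgeR quasi-likelihood adjusted p = 0.0245). Depth is argued against, since thinned counts gave 0.72 ± 0.14 (SE, edgeR quasi-likelihood adjusted p = 0.0192). With GC and length offsets the difference was 0.59 ± 0.15 (SE, edgeR quasi-likelihood adjusted p = 0.323), more than 0.5 times the first value, and the call ended because the estimate fell and its error grew, so that these trends are argued against as the whole cause but not as a part of it; over 15 alternatives the adjusted p ran from 0.000384 to 0.855. An unlabelled split of library preparation cannot be told apart from the dose: with the share of mt-Atp6 in mitochondrial counts as a covariate the value was 0.47 ± 0.15 (SE, edgeR quasi-likelihood adjusted p = 0.9998). A low ratio of mt-Atp6 to mt-Nd4l was found in 7 of 10 libraries of Both_10Cyp and 1 of 12 of Both_0.3Cyp, in 3 of 8 of Maternal_10Cyp, 3 of 12 of Maternal_0.3Cyp and 1 each of the paternal groups, and in 0 of 12 of Ctrl.

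At dose 10 the effect of both parents departed from the sum of the single effects for 3904 genes (2370 with GC and length offsets). Unequal depth is argued against, as thinned counts gave 3825, but not a separate deep run. What stays open is that Ctrl stands apart from all exposed groups, whichever parent was exposed, so that the sum of 2 effects counts 1 shift double: Both_10Cyp against the mean of Maternal_10Cyp and Paternal_10Cyp, which uses no Ctrl library, gave 0 genes by edgeR (1133 at an unadjusted p under 0.05). A difference in stage may contribute, with 2585 genes under the globin covariate, and a real limit to the combined effect of both parents remains untested.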

How the results depend on the processing

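The embryonic globin covariate, the thinned counts, the GC and length offsets and the removal of libraries high in embryonic globin or diencephalon markers were tests chosen after seeing the data; the others were planned. Values that follow are counts of genes, by edgeR unless a tool is named, for results that moved by more than 1.5 times; the cause was not tested. In parentheses after a 0 stands the count at an unadjusted p under 0.05. With DESeq2 size factors, without the filter and in thinned counts the 6 counts against Ctrl stayed within 1.5 times, and that of Maternal_10Cyp did so under all alternatives but batch 1 alone and 2 surrogate variables. With DESeq2 size factors in edgeR the counts were 18 for dose among paternal groups and 1 for non-additivity at 0.3. Without the filter on counts the counts were 17 for dose among paternal groups, 5 for maternal against paternal at 0.3 and 1 for non-additivity at 0.3. By DESeq2 the counts were 1085 for Both_10Cyp, 58 for dose among paternal groups, 6 for dose among maternal groups, 3 for dose where both parents were exposed and 5 for maternal against paternal at 0.3. DESeq2 also gave 410 for non-additivity at 0.3, 2 for maternal against paternal at 10, 2 for sex by exposure and 5 for batch by exposure. By limma voom with quality weights the counts were 5290 for Both_0.3Cyp, 952 for Both_10Cyp, 5727 for any exposure, 206 for dose among paternal groups and 436 for dose among maternal groups. Limma also gave 2 for dose where both parents were exposed, 0 (886) for maternal against paternal at 0.3, 773 for non-additivity at 0.3, 6124 for non-additivity at 10 and 84 for batch by exposure. There the sign turned for Mab21l2 (Paternal_0.3Cyp, -0.017). When only the groups compared were fitted the counts were 0 (3928) for Paternal_0.3Cyp, 4807 for Both_0.3Cyp, 0 (583) for dose among paternal groups, 2 for dose where both parents were exposed and 0 (265) for maternal against paternal at 0.3. Without the batch term the counts were 1880 for Paternal_10Cyp, 55 for Both_10Cyp, 2 for dose among paternal groups and 0 (434) for dose where both parents were exposed. In batch 1 alone the counts were 4 for Paternal_0.3Cyp, 0 (1550) for Maternal_0.3Cyp, 0 (2651) for Both_0.3Cyp, 187 for Paternal_10Cyp, 465 for Maternal_10Cyp and 0 (646) for Both_10Cyp. Batch 1 also gave 0 (2023) for any exposure, 0 (2051) for dose among paternal groups, 0 (629) for dose where both parents were exposed, 0 (300) for maternal against paternal at 0.3, 494 for non-additivity at 10 and 9 lists in Both_10Cyp. In batch 2 alone the counts were 1313 for Paternal_0.3Cyp, 1323 for Both_0.3Cyp, 2142 for Both_10Cyp and 855 for any exposure. Batch 2 also gave 1 for dose among paternal groups, 0 (1059) for maternal against paternal at 0.3, 1 for non-additivity at 0.3 and 553 for non-additivity at 10. With 2 surrogate variables the counts were 0 (1592) for Paternal_0.3Cyp, 0 (1070) for Maternal_0.3Cyp, 0 (1445) for Both_0.3Cyp, 158 for Paternal_10Cyp, 448 for Maternal_10Cyp and 13 for Both_10Cyp. The same setting gave 43 for any exposure, 21 for dose among paternal groups, 2 for dose where both parents were exposed, 322 for non-additivity at 10 and 14 lists in Both_10Cyp. There the sign turned for Epha10 (Maternal_0.3Cyp, 0.040), Creg2 (Maternal_0.3Cyp, 0.030), Lhx2 (Maternal_10Cyp, -0.024), Zim1 (Maternal_10Cyp, 0.017), Gad1 (Maternal_10Cyp, 0.057), Slc32a1 (Maternal_10Cyp, 0.0023), Gpr17 (Maternal_10Cyp, 0.10), Penk (Maternal_10Cyp, 0.071) and Phgdh (Maternal_10Cyp, -0.012).

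The replicate number served as a block, although the numbers do not pair libraries across groups, and the counts that moved were 342 for Both_10Cyp, 3 for dose where both parents were exposed, 0 (933) for maternal against paternal at 0.3, 99 for non-additivity at 0.3 and 2 for batch by exposure. Camera with an estimated correlation called 0 lists in each of the 6 exposed groups. Over genes with a mean CPM of at least 10, the median correlation of log2 fold changes between exposed groups was 0.918 in place of 0.757.

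With the embryonic globin covariate the counts were 44 for Paternal_0.3Cyp, 170 for Maternal_0.3Cyp, 10 for Both_0.3Cyp, 132 for Both_10Cyp and 578 for any exposure. The covariate also gave 14 for dose among paternal groups, 1 for dose among maternal groups, 2 for dose where both parents were exposed, 3 for maternal against paternal at 0.3 and 2585 for non-additivity at 10. There the sign turned for Hba-x (Paternal_0.3Cyp, -0.078). Without the 3 libraries high in embryonic globin the counts were 1788 for Paternal_0.3Cyp, 43 for Both_10Cyp, 3 for dose among paternal groups, 0 (779) for dose where both parents were exposed and 2 for maternal against paternal at 0.3. There the sign turned for Hbb-y (maternal against paternal at 0.3, 0.013). Without the 5 libraries high in diencephalon markers the counts were 2175 for Paternal_0.3Cyp, 1770 for Paternal_10Cyp, 283 for Both_10Cyp, 0 (998) for dose among paternal groups, 1 for dose among maternal groups and 0 (597) for maternal against paternal at 0.3. With GC and length offsets the counts were 1499 for Paternal_10Cyp, 1928 for any exposure, 2 for dose among paternal groups and 1 for dose among maternal groups. The offsets also gave 0 (510) for dose where both parents were exposed, 0 (483) for maternal against paternal at 0.3, 4 for non-additivity at 0.3 and 2370 for non-additivity at 10. There the sign turned for Bcl11b (Maternal_10Cyp, 0.015). In counts thinned to the lowest total the counts were 0 (574) for maternal against paternal at 0.3 and 1 for non-additivity at 0.3. Leaving out each library in turn gave 2262 to 4960 genes for Paternal_0.3Cyp, 2166 to 4103 genes for Maternal_0.3Cyp, 2042 to 4013 genes for Both_0.3Cyp, 1709 to 3840 genes for Paternal_10Cyp, 5056 to 6235 genes for Maternal_10Cyp and 29 to 1625 genes for Both_10Cyp. The gene lists were not recomputed by DESeq2 or limma, without the batch term, with only the groups compared, in thinned counts or with libraries removed. With GC and length offsets, camera on ranked edgeR statistics made 118 of 133 calls of a list in a group again in the same direction and 0 in the opposite one. Lost were 4 for autism genes, 2 for erythroid markers, 1 for microglia, 1 for mitochondrially encoded mRNAs, 2 for oxidative phosphorylation, 3 for oxidative stress and 2 for upper-layer neurons. Other calls were gained. Within 1 batch the batch by exposure test gives no value, and neither do the joint tests and male against female when only the groups compared are fitted. Among named genes of the comparisons with Ctrl, those that lost the call and kept the direction numbered 25, 18, 20, 18, 116 and 14 with 2 surrogate variables, 25, 20, 20, 19, 136 and 20 in batch 1 alone and 23, 15, 20, 5, 31 and 12 with the globin covariate. The order is Paternal_0.3Cyp, Maternal_0.3Cyp, Both_0.3Cyp, Paternal_10Cyp, Maternal_10Cyp and Both_10Cyp. Of 50 genes changed 2-fold in simulated counts of the size of Both_10Cyp 48 were called.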

Other observations

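Ctrl replicate 7, labelled female, held 15 counts of the Y-linked gene Ddx3y, and its Y-linked genes together reached 2.17 percent of the mean of male libraries, where the next female library reached 0.123 percent.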
